A study of Homo sapiens with 13 samples.

How the data were processed

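FOXA1 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the human endometrial cancer cell lines Ishikawa and Hec1A. The labels describe 13 libraries, which are 6 FOXA1 ChIP libraries and 2 input libraries of Ishikawa, and 3 FOXA1 ChIP libraries and 2 input libraries of Hec1A. Input is sheared chromatin that was not immunoprecipitated. Per the labels' protocols, libraries were prepared with either of 2 kits. In Ishikawa, 2 ChIP libraries were prepared with TruSeq and 4 with ThruPLEX, and in Hec1A the numbers were 1 and 2. Both kits are mixed within each pool, so an effect of the kit could not be separated.

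Per the submitters' processing notes, Bowtie 1.1.2, SAMtools 1.3.1, HOMER 4.7.2 and the genome build hg19 were used. Per the file headers, the authors called peaks with the HOMER findPeaks program in its factor mode on the pooled ChIP tags of each line, which gave 1 list per line. A tag is the mapped 5′ end of a sequenced fragment. Each putative peak had to pass a tag threshold at a false discovery rate of 0.001, which was 88 tags in Ishikawa and 32 tags in Hec1A. It also had to exceed the surrounding 10000 bp by a fold of 4. The unique positions of its tags could lie at most a fold of 2 under the expected number. Per the file headers, Ishikawa peaks were also required to exceed the pooled Ishikawa inputs by a fold of 4. The recorded Hec1A command names no input, its header lists no input filter, and its list has no columns on input. The name given to the Hec1A list does refer to inputs. However, the local and clonality filters account for every peak removed between the 80046 putative and 13252 listed peaks. The recorded Hec1A call therefore removed no peak on input. Peak width was fixed at 353 bp in Ishikawa and 254 bp in Hec1A.

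The deposited signal is the tag count of a peak per 10000000 tags. The deposited focus ratio is a fraction that describes how tightly the tags surround the peak centre. The deposited findPeaks score is a tag number, and the deposited folds over the local region and over input are ratios of a peak's tags. The clonal fold is the fold by which the unique positions of a peak's tags lie under the expected number. The deposited p-value columns, which are Poisson p-values over local region and input per the file headers, took no part in the comparisons. The Ishikawa list also gives the authors' input signal per peak. These values are the authors' own, and scores and folds were used to rank, filter or describe peaks within their own list.

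Overlap was defined as at least 1 bp shared by the deposited intervals. It was compared with 10000 circular shifts of the Hec1A peaks within each chromosome, one-sided for more overlap. The 25% of peaks with the highest and the 25% with the lowest scores were compared with Fisher's exact test, two-sided, within each list. The share of peaks on each chromosome was compared between lists with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over chromosomes. Intervals of shares are 95% Wilson intervals, cover counting error, and treat peaks, or tags for shares of tags, as independent. The 8 peaks of highest score among shared, Ishikawa-only and Hec1A-only peaks are named, with shared peaks ranked by the mean of their ranks in both lists. This rule, the tests and part of the alternatives were fixed before the data were examined.

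The local background of a peak was computed as its signal divided by its fold over the local region. Peak-poor regions are chromosomes Y and M and positions inside or within 1 Mb of the largest interval without an Ishikawa peak on each chromosome. As this definition uses the Ishikawa list, the number of Ishikawa peaks in such regions is not independent of it. Windows of 10 Mb with at least 20 peaks were compared by Spearman and Pearson correlation. Their permutation p-values come from rotating 1 series of windows along the genome, and their intervals from 2000 bootstrap draws of chromosomes. Clonality was compared over score deciles by the Mantel-Haenszel common odds ratio. The local background, the windows, the regions and the split at a clonal fold of 1 were chosen after the data were seen.

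The overlap and chromosome procedures were tested on simulated lists. With 30% of peaks planted as shared, 30.7% were recovered, and with none planted the overlap was 0.921 times that of shifted peaks. Chromosomes with 1.5 times the peaks were called in 100% of cases over 100 simulations. Without an excess, 5% of simulations gave any call. The simulated peaks were drawn independently, as Fisher's exact test assumes, so clustering of peaks was not covered. Some called effects, such as an odds ratio of 1.20 on chromosome 3, were smaller than the planted excess.

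Values per library are not analysed here, so no replicate error, no leave-one-out analysis and no test between replicates could be given. No hg19 annotation or genome sequence was used here. The planned analyses of peak position relative to genes, of 17 fixed gene lists, of bound genes and of forkhead motifs were therefore not run, and peaks are given by hg19 position. Alternatives covered stricter thresholds, equal peak numbers, other overlap definitions, another null, autosomes alone, other rankings, clonality and peak-poor regions. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.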

Results

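FOXA1, a forkhead transcription factor that opens chromatin for hormone receptors, was mapped by ChIP-seq in the endometrial cancer cell lines Ishikawa and Hec1A. The Ishikawa list was called on 6 pooled ChIP libraries that held 343739762 tags, with 2 pooled inputs. The Hec1A list was called on 3 pooled ChIP libraries that held 143055568 tags, and 2 Hec1A input libraries are labelled. Each line has 1 list, so the values below have no replicate error, and tests on peaks compare these 2 lists. Coordinates are those of hg19.

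The first question was how many sites FOXA1 occupied in each line. The Ishikawa list held 54855 peaks and the Hec1A list 13252 peaks, a ratio of 4.14. Peaks held 9.66% of Ishikawa tags (95% Wilson interval 9.655% to 9.662%) and 1.12% of Hec1A tags (1.116% to 1.119%). These intervals cover the counting error of tags alone and leave out variation between libraries. The median peak had a signal of 9.69 tags per 10000000 in Ishikawa and 4.96 in Hec1A, and a fold over the local region of 6.93 and 5.71.

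The lists passed different filters, so their lengths do not compare binding alone. In Ishikawa, 246198 of 352089 putative peaks (69.9%) were removed on input. The Hec1A header lists no such step for its 80046 putative peaks, although the name given to the list refers to inputs. The local filter removed 41790 of them and the clonality filter 25004, which leaves exactly the 13252 listed. The recorded Hec1A call therefore removed no peak on input. Of the peaks that reached the clonality filter, 65.4% were removed in Hec1A (25004 of 38256) and 18.7% in Ishikawa (12587 of 67442). At a fold over the local region of at least 8, a threshold chosen after the data were seen, 21990 Ishikawa peaks and 3442 Hec1A peaks were left. At a fold over input of at least 8, 26646 Ishikawa peaks were left.

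The second question was which sites the lines shared. A total of 7012 Hec1A peaks overlapped an Ishikawa peak, which was 52.9% of the Hec1A list (95% Wilson interval 52.1% to 53.8%) and 12.8% of the Ishikawa list (12.5% to 13.1%). Shifted Hec1A peaks overlapped in 147.8 cases on average and in at most 191, so the observed overlap was 47.4 times higher. The circular-shift permutation p was 0.0001, the smallest that 10000 shifts can give. Shifted peaks can fall where reads cannot map or where neither list has signal, so this null is easily exceeded. With local shifts of 50 to 500 kb the observed overlap was 38.85 times the shifted mean. Neither null separates FOXA1 binding from other signal common to both lists. Shared peaks held 56.4% of the Hec1A signal in peaks and 27.3% of the Ishikawa signal in peaks. When the Ishikawa list was reduced to its 13252 highest-scoring peaks, 29.9% of the peaks of either list were shared, 109 times the shifted mean. Over the alternatives this ratio ranged from 15.2, with centres within 1 kb, to 157.5.

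The shared sites of highest rank lay on several chromosomes. The first was at chromosome 17, 39114408 to 39114662 in Hec1A, with a fold over the local region of 67.3 there and 124 in Ishikawa. The next was at chromosome 9, 128300376 to 128300630, with folds of 82.7 and 150. Further sites on chromosome 17 were at 79367801 to 79368055, with folds of 69.5 and 158, and at 74637755 to 74638009, with folds of 33.3 and 120. The others were at chromosome 12, 31902347 to 31902601, chromosome 5, 123997126 to 123997380, chromosome 8, 52811599 to 52811853, and chromosome 1, 3541230 to 3541484. Ranks by score were not adjusted for regional tag levels, here or for the peaks named below. The sites on chromosomes 17 and 5 lie in segments of raised Hec1A local background, and Ishikawa input was raised on chromosome 12.

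The Ishikawa peak of highest score, at chromosome 12, 71849170 to 71849522, had no Hec1A partner. Its fold over input was 571, and the nearest Hec1A peak lay 385 kb away. The next Ishikawa-only peaks were at chromosome 7, 47022419 to 47022771, with a fold over input of 1373, at chromosome 18, 31382842 to 31383194, with 276, and at chromosome 5, 123935355 to 123935707, with 484. That last peak had a Hec1A peak 2.77 kb away. The remaining 4 were at chromosome 7, 146236909 to 146237261, chromosome 14, 25550892 to 25551244, chromosome 2, 67264790 to 67265142, and chromosome 10, 112389361 to 112389713.

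The 8 Hec1A-only peaks of highest score lay in peak-poor regions. They were at chromosome 1, 121485074 to 121485328, at chromosome 6 between 58777093 and 58779029 (3 peaks), at chromosome 7, 61969221 to 61969475, at chromosome 10, 42385091 to 42385345, and on the mitochondrial chromosome at 84 to 338 and 15998 to 16252. Peak-poor regions held 267 Hec1A peaks. Those near the largest peak-free intervals made up 1.75% of the list and held 11.3% of its signal in peaks. Outside these regions, a selection made after the values were seen, the Hec1A-only peaks of highest score were at chromosome 5, 124613273 to 124613527, with a fold over the local region of 43.2, and chromosome 1, 91852700 to 91852954, with 40.3. Their focus ratios were 0.962 and 0.635, and the first had an Ishikawa peak 2.19 kb away.

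Sharing rose over the score deciles of both lists, but not up to the top of the Hec1A list, where 77.8% of the 1000 highest-scoring peaks and 69.0% of the 100 highest-scoring peaks had a partner. In Ishikawa these shares were 47.4% and 54.0%. Of the Hec1A list, 74.3% of the 25% of peaks with the highest scores and 21.9% of the 25% with the lowest scores had a partner, an odds ratio of 10.3 (95% interval 9.21 to 11.6). In the Ishikawa list the highest and lowest 25% had shares of 29.5% and 2.41%, an odds ratio of 16.9 (15.1 to 19.0). Both p-values of Fisher's exact test were too small for double precision. Ranked by normalized tag count, the Hec1A shares were 71.3% and 46.0%, a difference of 25.3 points in place of 52.4. Among Hec1A peaks with a clonal fold of 1 or less, the difference was 30.9 points. Ranked by fold over input, the Ishikawa shares were 23.7% and 5.99%, an odds ratio of 4.88 (4.50 to 5.29) and a difference of 17.7 points in place of 27.1.

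**Figure D1:**
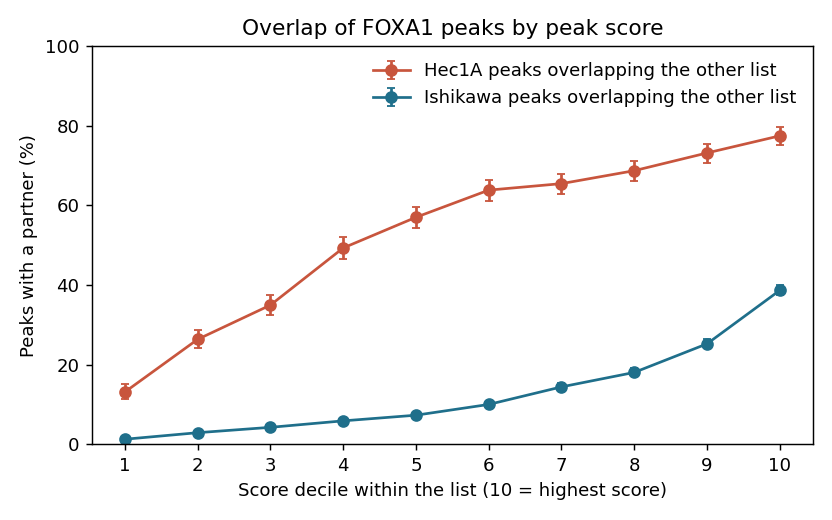
Share of peaks with a partner in the other list, in percent, by score decile within each list. Bars are 95% Wilson intervals, and the share rises from 13.1% to 77.4% in Hec1A and from 1.26% to 38.6% in Ishikawa.

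Clonality separated the Hec1A peaks. The clonal fold compares the unique positions expected for a peak's tags with those they occupy, and high values mark tags stacked on few positions. Of 9433 Hec1A peaks with a clonal fold of 1 or less, 64.4% had a partner (95% Wilson interval 63.4% to 65.3%). Of 3819 Hec1A peaks with a higher clonal fold, 24.6% had one (23.2% to 25.9%). The Ishikawa shares were 15.7% and 4.14%. This split was chosen after the data were seen.

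**Figure D2:**
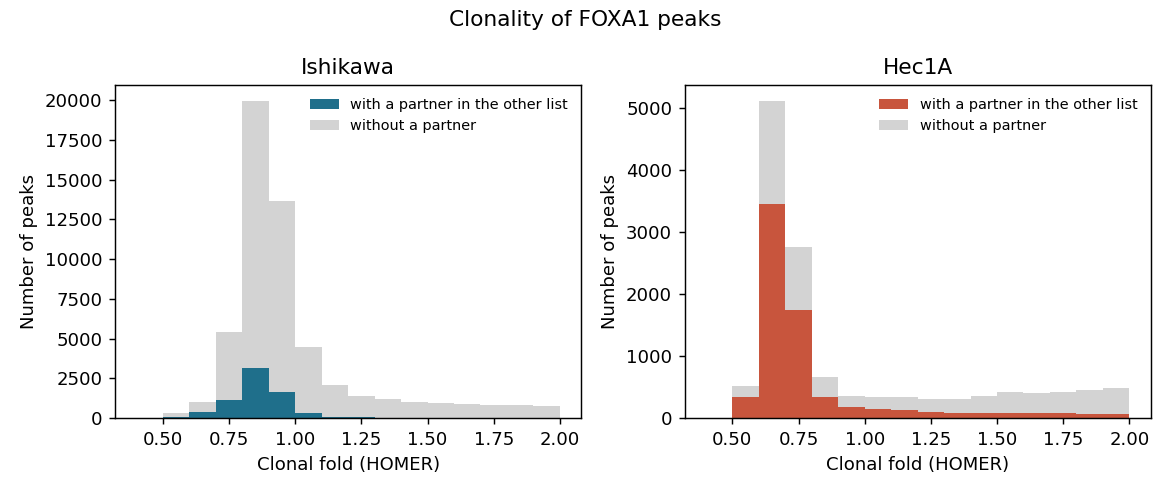
Number of peaks by clonal fold in each list, with peaks that have a partner in colour and the others in grey. Hec1A peaks gather at a clonal fold of 0.6 to 0.8, and 3819 of them lie above 1.

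The third question was whether the peaks were spread differently over the chromosomes. Hec1A had a larger share of its peaks on chromosomes 19, 17, 16, 22 and 20, and a smaller share on chromosomes 4, 13 and 18. Chromosome 19 held 4.06% of Hec1A peaks and 2.31% of Ishikawa peaks, an odds ratio of 1.78 (95% interval 1.61 to 1.98, adjusted p = 3.2e-25, Fisher's exact test). Chromosome 17 held 5.39% and 3.14%, an odds ratio of 1.76 (1.61 to 1.92, adjusted p = 3.7e-31, Fisher's exact test). Chromosome 4 held 5.20% and 7.32%, an odds ratio of 0.694 (0.639 to 0.754, adjusted p = 3.2e-18, Fisher's exact test). Of 25 chromosomes tested, 16 passed an adjusted p of 0.05, with 8 higher and 8 lower in Hec1A. Those higher include chromosome Y, with 32 Hec1A peaks and 1 Ishikawa peak (odds ratio 132.8, 95% interval 18.1 to 971.8, adjusted p = 3.9e-21, Fisher's exact test), and the mitochondrial chromosome, with 3 and 0. Of the Hec1A peaks on chromosome Y, 81.3% had a clonal fold above 1, and 6 were left at a clonal fold of 1 or less. The chromosome Y call rests on where tags were placed and does not show that FOXA1 bound there. The mitochondrial call was lost with equal peak numbers (adjusted p = 0.33, Fisher's exact test) and at a fold of at least 8 over input (adjusted p = 0.061) or over the local region (adjusted p = 0.28).

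Chromosomes 4, 16, 19 and 20 kept their direction and passed the threshold in each of 6 settings. Each setting used all or part of the same peak lists. None applied an input filter to Hec1A or adjusted for regional background. A call kept in all 6 settings therefore does not separate FOXA1 binding from unlike filters or regional tag levels. Chromosome 3 held 8.58% of Hec1A peaks and 7.24% of Ishikawa peaks, an odds ratio of 1.20 (1.12 to 1.29, adjusted p = 7.7e-07, Fisher's exact test). Among peaks with a clonal fold of 1 or less, its direction turned to an odds ratio of 0.827 (adjusted p = 0.00016, Fisher's exact test). Of the Hec1A peaks on chromosome 3, 50.6% had a clonal fold above 1 and 39.5% had an Ishikawa partner. At a fold over the local region of at least 8, 8 chromosomes passed the threshold. Of the 16 calls 10 were lost, among them chromosomes 13, 17, 18 and 22, and chromosomes 5 and 10 were gained.

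**Figure D3:**
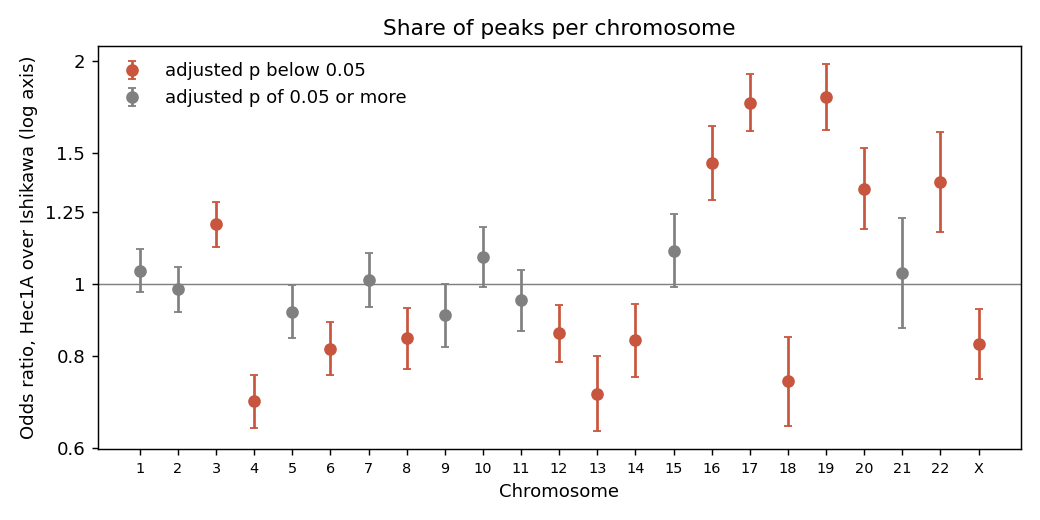
Odds ratio of the share of peaks on each autosome and chromosome X, Hec1A over Ishikawa, on a log axis, with 95% intervals; chromosomes Y and M are not drawn. Red points have an adjusted p below 0.05, and of the chromosomes drawn 17 and 19 stand highest at 1.76 and 1.78.

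The files also hold background levels along the genome. Pooled input tags per Ishikawa peak averaged 7.88 on chromosome 12 and 5.31 on the other autosomes. The median local background of Hec1A peaks with a clonal fold of 1 or less was 1.08 tags per 10000000 on chromosome 3 and 0.765 on the other autosomes, a ratio of 1.41 (95% bootstrap interval 1.37 to 1.46). It was also higher on chromosome 17 from 20 Mb, with a ratio of 1.48 (1.40 to 1.53), on chromosome 5 from 120 Mb, with a ratio of 1.51 (1.43 to 1.67), and on chromosome 2 from 100 to 150 Mb, with a ratio of 1.44 (1.34 to 1.63). It was lower on chromosome 9 below 40 Mb, with a ratio of 0.661 (0.620 to 0.712). These segments were picked from the same values and are not all that were raised. The windows starting at 40 Mb, for example, had a median of 1.26 on chromosome 7 and 1.02 on chromosome 19.

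**Figure D4:**
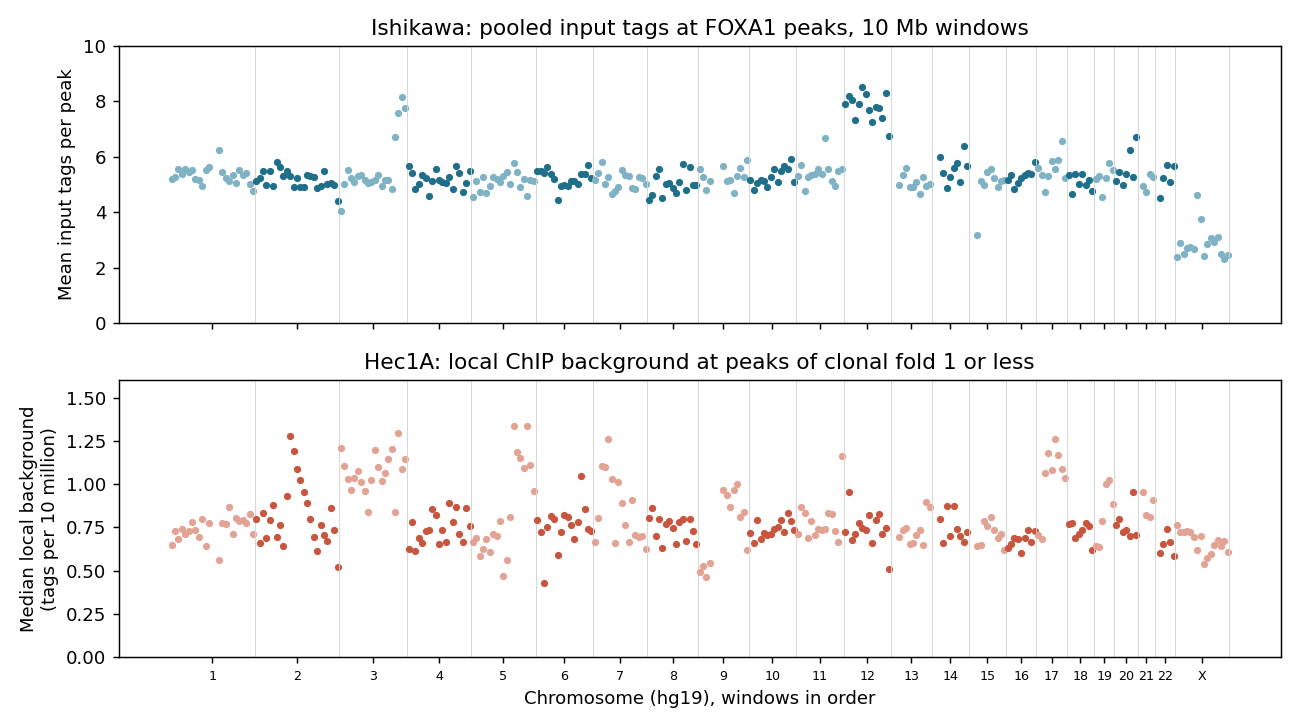
Mean pooled input tags per Ishikawa peak (top) and median local background of Hec1A peaks with a clonal fold of 1 or less, in tags per 10000000 (bottom), in windows of 10 Mb with at least 20 Ishikawa peaks. Input is raised along chromosome 12, and Hec1A background is raised along chromosome 3.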

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

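The tests of clonality, of peak-poor regions, and of local background were chosen after the result was seen, except that against the Ishikawa background, whose outcome was stated before it was computed.

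The level of input tags per peak enters the comparisons between the lines through the fold over input, and was not itself compared there. It stood above that of the other autosomes on 2 segments of the Ishikawa genome. The ratio was 1.48 on chromosome 12 (95% bootstrap interval 1.46 to 1.51, 2940 peaks), and its 14 windows ranged from 6.75 to 8.53 tags per peak. On chromosome 3 from 160 Mb the ratio was 1.39 (1.34 to 1.43, 846 peaks). Input was read at called peaks alone, and both segments were picked from these values.

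Hec1A peaks of high clonality had an Ishikawa partner less often. Lower score as the whole cause is argued against by a common odds ratio of 0.333 over score deciles (95% interval 0.303 to 0.365), and position in peak-poor regions by 0.351 outside them (0.319 to 0.386). The same odds ratio in the Ishikawa list was 0.701 (0.637 to 0.772). Repeated reads on few positions and binding specific to Hec1A both stay open, since the clonal fold itself marks repeated reads and 0.701 does not set them apart.

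Hec1A peaks without a partner were more frequent where the Hec1A local background was high, with a Spearman rho of 0.359 over 259 windows (0.118 to 0.562; Pearson r = 0.493; permutation p = 0.0039, adjusted 0.0055 over 7 relations, the smallest the rotations can give). Without chromosomes 3, 5 and 17 rho was 0.187 (0.0133 to 0.348), with raised windows elsewhere, such as on chromosomes 2, 7 and 19, still included. Features shared by both lines were predicted to give a rho above 0 with the Ishikawa background, and it was -0.237 (-0.382 to -0.0741). This cannot decide against them, since the share without a partner depends on the Ishikawa peaks themselves. On chromosome 12 the Ishikawa background was 1.49 times that of other autosomes, and 62.2% of Hec1A peaks had a partner. Additional binding sites stay open: rho was -0.0586 among peaks with a clonal fold of 1 or less (-0.194 to 0.0648), but this leaves out peaks whose share itself rose with the background (rho 0.515). Copy number gain, in a list called without an input filter, is a candidate explanation. It stays open because Hec1A input is not analysed here and 0.359 restates the pattern.

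Of the 100 highest-scoring Hec1A peaks, 18 lay in peak-poor regions and had no partner. Focused binding like that of other strong peaks is argued against by their median focus ratio of 0.705 against 0.972, a difference of -0.268 (95% bootstrap interval -0.336 to -0.127). Of the 82 other peaks 69 had a partner, so region and lack of a partner were not separated. Neighbouring peaks, such as the 3 on chromosome 6, are not independent. Absence of an input filter, which the header counts show for this list, could account for them but remains undecided as their cause. The regions near peak-free intervals were defined from the Ishikawa list, so their count decides nothing. The 3 mitochondrial peaks among 100 against 0 in Ishikawa gave p = 0.25 (Fisher's exact test). This test could not decide either, since the whole Hec1A list holds only these 3 and the Ishikawa list 0. A smaller p was therefore out of reach.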

How the results depend on the processing

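Alternatives on fold over the local region, clonality and peak-poor regions were chosen after seeing the data. Over results and settings, 98 alternatives were computed and 78 kept their direction and side of the threshold, or stayed within 1.5 times for a count. The share of Hec1A peaks with a partner ranged from 29.9% with equal peak numbers to 64.4% among Hec1A peaks with a clonal fold of 1 or less, and exceeded the shifted overlap in each of 11 alternatives. At a fold over the local region of at least 8, peak numbers fell to 21990 in Ishikawa and 3442 in Hec1A, and 8 chromosomes passed the threshold in place of 16, with 10 calls lost and 2 gained. At a fold over input of at least 8, 26646 Ishikawa peaks were left. The lower peak numbers follow from the thresholds, and for the chromosomes the cause was not tested.

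The direction turned and passed the threshold on chromosome 3 at a clonal fold of 1 or less (odds ratio 0.827, adjusted p = 0.00016, Fisher's exact test) and on chromosome X with equal peak numbers (2.11, adjusted p = 6e-17, Fisher's exact test). On chromosome X the Hec1A share stayed at 3.01%, and the Ishikawa share fell from 3.61% to 1.45% when its highest-scoring peaks were kept. At a fold over the local region of at least 8, chromosomes 3, 6 and 8 crossed an odds ratio of 1 without passing the threshold, at 0.860, 1.01 and 1.03 (adjusted p = 0.12, 0.91 and 0.78, Fisher's exact test). The cause was not tested. The stricter input threshold was not applied to Hec1A, whose list holds no fold over input. Alternatives for gene position, gene lists, bound genes and motifs, and leaving out libraries, were not run. No paired analysis was possible because the libraries of each line were pooled. The lists rest on 143055568 tags in Hec1A and 343739762 in Ishikawa and were not brought to equal depth, so weak Hec1A sites can be missing at this depth.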

Other observations

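The tests and selections here were chosen after the data were seen. Ishikawa peaks gathered in clusters. With peak centres linked at up to 10 kb, 131 clusters held 5 or more peaks, against a mean of 38.9 and a highest of 55 in 100 uniform random placements. The number depended on the link: it was 963 at 20 kb (random mean 356) and 1 at 5 kb (random mean 3.29), where there was no excess. Uniform placement ignores regions where reads cannot map, and their effect on the excess was not measured.

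The cluster with the most peaks, at chromosome 4, 40508077 to 40567055, held 9 Ishikawa peaks, of which 3 had a Hec1A partner. Of the 5 clusters of 8 peaks, that at chromosome 1, 151933322 to 151974587, had 3 Hec1A partners. The others had 0, at chromosome 14, 68716504 to 68762264, at chromosome 18, 24028863 to 24070413 and 20421957 to 20463898, and at chromosome 6, 134324080 to 134362493. The cluster at chromosome 1, 172291614 to 172329999, held 7 peaks with a summed signal of 770.6 tags per 10000000, and 2 of them had a partner. Before adjustment for score, Ishikawa peaks in clusters of 5 or more had a partner more often than single peaks, at 16.9% against 12.6%. Over score deciles the direction was the opposite, with a common odds ratio of 0.698 (95% interval 0.569 to 0.857).

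The score order of Ishikawa peaks differed between chromosomes of high and low input. Chromosome 12 held 5.36% of the Ishikawa list and 8.84% of its 13252 highest-scoring peaks. Chromosome X, where input tags per peak were 0.525 times those of the autosomes (95% bootstrap interval 0.509 to 0.539), held 3.61% and 1.45%. Over 284 windows, Ishikawa input tags and local background were correlated with a Spearman rho of 0.602 (0.443 to 0.745). The share of Ishikawa peaks with a clonal fold above 1 fell with input, with a rho of -0.441 (-0.556 to -0.331).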
